A study of Mus musculus with 2 samples.

How the data were processed

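Open chromatin was measured by ATAC-seq in whole hearts of B6NCrl mouse embryos at 16.5 days of gestation. Each sample pooled embryos of both sexes, and the samples formed 1 group of 2 biological replicates, so no contrast between conditions could be made.

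The authors deposited peak lists on the mouse build mm10, per the labels, and no read counts or coverage tracks were used. The aligner, the peak caller and their versions are not given in the sources used here. Each peak carried a signal value, a deposited quantity of the caller whose scale is not stated, and it was used as given. Each summit also carried a deposited -log10 p and a -log10 q from the caller, neither of them normalized for depth. The ranked lists carried a deposited score, the -log10 of the local and global irreproducible discovery rate (IDR). The global IDR is the expected share of peaks, down to a given rank, whose ranks are not reproducible between the compared lists. The local IDR is the like probability for a single peak. The ranked lists thus hold peaks present in both compared lists. These lists also held the deposited -log10 p of each peak in both compared lists. For each replicate the deposited files held a list thresholded on IDR between pseudoreplicates of that sample and a relaxed list of pseudoreplicated peaks. For both replicates together they held the conservative IDR list, made from the comparison of the biological replicates and called the joint list here. They also held a list from pooled pseudoreplicates and a relaxed list of replicated peaks. The joint list and the replicates' own lists were thresholded on different comparisons. A joint peak missing from a replicate's own list was therefore not shown to be absent from that replicate. Every summit of the thresholded lists had a global IDR of 0.05 or less in its ranked list. The thresholded lists also derived from a further file that the sources do not describe, and some regions of the ranked lists are missing from them.

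Depth is unknown for both samples, because the lists state no read totals. No counting interval or detection limit could therefore be given for any peak, and a gene without a peak was not shown to be closed. The spread between the 2 replicates is the only error available, given as mean ± SD with n = 2.

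Summits that shared an interval were merged to 1 peak per interval, with the highest summit and its signal value kept. That choice was made after the files were seen, and using every summit as a peak was added as an alternative. Positions were compared with the GRCm38 sequence and the protein-coding genes of GENCODE M21. A promoter peak had its summit within 1000 bp of a protein-coding transcription start site. In the counts per gene, such a peak was counted for every gene with a start site in that range. All other peaks are called distal, which includes peaks at the start sites of noncoding genes. Distal peaks were classed by summit as exon, intron or intergenic, where intergenic means outside protein-coding genes. A distal peak was assigned to the gene with the nearest such start site, if this lay within 100 kb. Single high peaks and clusters were instead named by the nearest such gene at any distance, which does not link them to that gene.

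Replicate peaks counted as shared when at least 50% of a peak's length lay in peaks of the other replicate. The same count was made after 100 random circular shifts along the chromosomes. The counts of shared peaks by own interval code and by bedtools 2.31.1 were equal. Signal values were compared at peaks matched 1 to 1, by Spearman's and Pearson's correlation across peaks, which are not independent replicates, so no p was computed. Peaks of 1 replicate with no base in the other's relaxed list were counted as restricted.

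For 18 gene lists, the share of members with a promoter peak was ranked among 10000 random lists matched on quintiles of the promoter's observed over expected CpG ratio. The CpG ratio was taken over 500 bp to each side of the gene's 5'-most start site, whereas a promoter peak could lie at any of its start sites. Matching could therefore refer to another start site than the one with the peak. The number of start sites per gene was not matched. The number of distal peaks per member was ranked among 10000 random lists matched on 10 classes of the length of genome nearest to the gene. A list stood apart above the 97.5th or below the 2.5th percentile, and 36 such comparisons were made without correction. Some genes belong to several lists, so these comparisons are not independent. The lists covered the sarcomere, cardiac transcription factors, calcium handling and conduction, fatty acid use and energy, and atrial and ventricular genes. Further lists held endothelial and endocardial, fibroblast, epicardial and valve, smooth muscle and pericyte, erythroid, immune, and neural crest, glia and neuron genes. The rest were brain, liver, lung and gut epithelium, skeletal muscle, housekeeping genes and olfactory receptors. All members of all lists were found in the annotation.

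Consensus sequences of 24 transcription factor families were searched on both strands within 100 bp of distal summits. Matches were compared with windows of equal size centred 1000 bp to each side and free of peaks. Distal peaks no more than 12.5 kb apart were stitched into clusters and ranked by summed signal value, and the 20 highest were compared with 10000 random draws. Peaks per Mb were computed for each chromosome.

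The genes named were set by rule. For each list these were the 2 members with the highest and the 1 with the lowest summed signal value, and cardiac transcription factors with no promoter peak. The rule also took the 5 highest promoter and distal peaks found in both replicates, the 10 highest clusters and the 2 highest restricted peaks of each replicate. Nppa, Nppb, Myh6, Myh7, Nkx2-5, Gata4, Tbx5, Hand2, Tnnt2, Myl2, Myl7, Wt1, Cdh5, Gata1, Alb, Foxg1 and Myod1 were fixed in any case. Genes named outside this rule were chosen after their values were seen, and each is marked so. The gene lists, consensus sequences, comparisons, naming rule and most alternatives were chosen before the data were examined. The tolerance of 0.05 for a changed correlation and the choice of GATA and MEF2 as the leading motifs were set later.

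The alternatives were a stricter cut at the upper 50% of peaks by signal value, the relaxed lists, the pooled pseudoreplicate list, and each replicate left out. Other overlap rules, promoter windows, start sites, gene assignments, matching, motif backgrounds and stitching distances were also tried. Alternatives added after seeing the data were every summit as a peak, the 5'-most start site of each gene, clusters without mitochondria-like peaks or of at least 2 peaks, and the X chromosome ratio without each replicate. Peak sequences were aligned to the mitochondrial genome at 90% identity or more, and further copies were counted at 90% identity over 80% of a peak's length. Sequences were aligned with BLAST 2.17.0 and read with samtools 1.23.1. Calculations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1, and plots used Matplotlib 3.10.9.

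The procedures were tested on simulated data. An overlap of 79.9% was recovered as 80.1%, a promoter share of 30% as 30%, and an SD of log2 ratios of 0.43 as 0.43. Of 200 unchanged lists 7% stood apart, against 5% by construction, and 99% of 100 lists of 22 genes with doubled counts were found. The simulated counts per gene were higher than the 0.474 distal peaks per gene of the joint list. The 99% therefore does not carry over to the real lists, and a list within random was not shown to lack a difference. A motif planted in 31.2% of windows was found in 31.4%, a motif that was not planted gave a log2 ratio of -0.09, and 30 of 30 planted clusters were recovered. Peaks on scaffolds outside the assembled chromosomes were left out of all comparisons, since the gene annotation used covers the chromosomes.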

Results

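The samples were whole hearts of mouse embryos at E16.5, late in fetal heart development, from the strain B6NCrl with both sexes pooled. ATAC-seq, in which a transposase inserts adapters into accessible DNA, gave 1 group of 2 biological replicates. The labels name the tissue and stage and state no further question. Open regions were therefore described by the genes and sequences they held, against matched random sets, and by how far the replicates shared them. Replicate 1 had 17950 peaks, replicate 2 had 17389, and the joint list of both replicates had 23953. The joint peaks had a median width of 742 bp and covered 18.7 Mb, or 0.684% of the genome. Read totals were not available, so the depth is unknown and peak heights are deposited signal values without a counting interval.

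Most open regions were shared by both heart pools, and their heights were close. Of the peaks of replicate 1, 79.5% lay for at least 50% of their length in peaks of replicate 2, and 82.7% did so in the other direction. The mean of both directions was 81.1%, against 0.483% on average and 0.602% at most after random shifts. At 14377 matched peaks Spearman's correlation was 0.876 and Pearson's correlation of log2 signal values was 0.880, across peaks that are not independent replicates. The SD of the log2 ratio was 0.24, which is a 1.18-fold spread for a single peak. In the joint list 57.3% of peaks, or 13732, were found in both replicates' own lists.

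**Figure D1:**
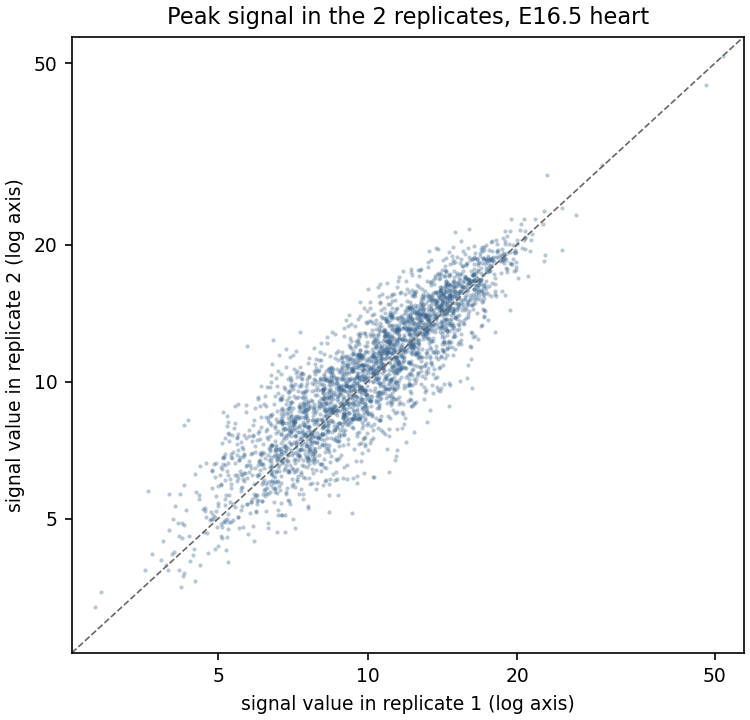
Signal values of peaks matched between the replicates, replicate 1 on the horizontal and replicate 2 on the vertical log axis, with every 5th matched peak drawn as a point. The points follow the line of equality, with a Spearman correlation of 0.876 over all 14377 matched peaks.

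Peaks restricted to 1 replicate were few and low. Replicate 1 had 311 peaks (1.73%) without any base in the relaxed list of replicate 2, and replicate 2 had 196 (1.13%) without any in that of replicate 1. Their median signal values were 5.90 and 6.14, against 9.39 and 9.77 for all peaks of those replicates. The highest in replicate 1 lay at the promoters of Ankrd17 (chromosome 5, 90339571 to 90339943, signal value 12.53) and Trpm3 (chromosome 19, 22138990 to 22139517, 11.9). The highest in replicate 2 lay at the promoter of 1810009A15Rik (chromosome 19, 8888471 to 8889039, 12.6) and in an intron near Ssh2 (chromosome 11, 77366068 to 77366340, 10.4). The total of 507 became 6194 when the other replicate's thresholded list was searched instead, and 17 among the upper 50% of peaks by signal value.

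Open chromatin was concentrated at promoters. In the joint list 49.1% of peaks had their summit within 1000 bp of a protein-coding start site, 19.2-fold more than the 2.56% of shifted peaks. In the replicates' own lists the share was 59.6% ± 0.977 (SD, n = 2). Introns held 24.01% of joint peaks, regions outside protein-coding genes 24.3%, and exons 2.63%, against 35.3%, 59.0% and 3.16% of shifted peaks. Of 630 exon peaks, 228 had their summit in coding sequence. Among the highest 10% of joint peaks by signal value 89.6% were promoter peaks, and among the lowest 10% 31.7% were. The promoter share was 25.4% in the relaxed list.

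The highest promoter peaks lay at genes outside the fixed lists. The first was at Kifap3, a subunit of the kinesin-2 motor (chromosome 1, 163779281 to 163780115), with a signal value of 27.97 in the joint list and 25.6 ± 1.22 (SD, n = 2) in the replicates. Next were Cbwd1 at 27.5, Cdc25c, a phosphatase that promotes entry into mitosis, at 26.5, Tmem218 at 26.3, and Tars, the threonyl-tRNA synthetase, at 26.1. Of 21853 protein-coding genes, 11812 (54.1%) had a promoter peak. This share rose from 6.29% in the quintile with the lowest promoter CpG ratio to 92.8% in the quintile with the highest. The highest distal peaks were nearest to Abcb11 (chromosome 2, 69355469 to 69355735) with a signal value of 59.4, Pak3 at 55.7, Gm5426 at 49.6, G6pd2 at 48.0 and Frmd4a at 40.3. All 5 were intergenic, and 86.7% of the peak near Gm5426, 86.8% of that near G6pd2 and 48.3% of that near Abcb11 aligned to the mitochondrial genome.

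Promoters of heart muscle genes were open more often than those of genes with like CpG content at the 5'-most start site. Of 25 sarcomere genes, which build the contractile apparatus, 23 (92%) had a promoter peak in the joint list, against a mean of 32.4% in matched random lists. In the replicates' own lists the share was 86% ± 2.83 (SD, n = 2). All 26 genes of fatty acid use and energy supply had one, against 54.5%, with 90.4% ± 2.72 (SD, n = 2) in the replicates. Cardiac transcription factors had one at 23 of 24 genes (95.8% against 73.0%), and genes of calcium handling and conduction at 20 of 25 (80% against 60.6%). The ventricular list had 13 of 15 (86.7% against 51.3%), and the housekeeping list, the comparison set of genes used in all cells, had 25 of 25 (100% against 76.0%). These 6 lists stood above the upper limit of random lists. They share members: among others, Myl2 and Myh7 of the ventricular list are sarcomere genes, Irx4 is a cardiac transcription factor and Gja1 a conduction gene.

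Within the replicates' own lists, the sarcomere, fatty acid, calcium and housekeeping lists also stood above random in both. The cardiac transcription factors, at 77.1% ± 2.95 (SD, n = 2), and the ventricular genes, at 60% ± 0 (SD, n = 2), lay within random in each. Restricted to the upper 50% of peaks by signal value, the fatty acid list alone stayed above random, and cardiac transcription factors fell to 37.5%, below random. The call also ended for calcium genes with a promoter window of 500 bp (72%) and for cardiac transcription factors with the 5'-most start site alone (83.3%).

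Among sarcomere genes, the highest summed signal values were at Actn2 and Xirp1. Actn2 (ENSMUSG00000052374.16, chromosome 13, 12269426 to 12340760) encodes the Z-disc protein alpha-actinin 2. Its promoter peak had a signal value of 9.17 in the joint list and 8.31 ± 1.11 (SD, n = 2) in the replicates. Xirp1, which encodes an actin-binding protein of the intercalated disc, had 5.12 and 4.71 ± 0.885 (SD, n = 2). Tnnt2, the gene of cardiac troponin T, had 8.67 and 8.38 ± 0.839 (SD, n = 2). The beta myosin heavy chain gene Myh7 (ENSMUSG00000053093.16, chromosome 14, 54970684 to 54994626) had 5.37, with 5.21 ± 0.296 (SD, n = 2) in the replicates. Myh6, the alpha heavy chain gene, had 3.83 in the joint list. Of the replicates' own lists, only that of replicate 2 held its promoter peak, at 3.73. No promoter peak was listed for Myom2, a gene of the M-band, or for Obscn, a giant sarcomere protein named after its value was seen.

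Among cardiac transcription factors, Mef2a (ENSMUSG00000030557.17, chromosome 7, 67231163 to 67372858) and Tead1 led in summed signal value in the joint list, at 86.1 and 71.2. The replicates gave 52.5 ± 12.1 and 46.1 ± 20.3 (SD, n = 2), the latter below Myocd at 51.5 ± 6.38, named after its value was seen. The promoter peak of Mef2a had 10.5 in the joint list and 10.1 ± 0.0285 (SD, n = 2) in the replicates, and that of Tead1 had 8.63 and 9.02 ± 1.71 (SD, n = 2). Nkx2-5, a homeodomain factor of cardiac progenitors and myocytes, had 11.1 and 10.7 ± 3.83 (SD, n = 2). Hand2, a basic helix-loop-helix factor of ventricular development, had 7.84 and 7.66 ± 0.988 (SD, n = 2). Tbx5 and Irx4 had low promoter peaks of 3.98 and 4.25 in the joint list and none in either replicate's own list. Hand1 was the 1 member without a promoter peak there, and the relaxed list held one at 4.85.

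Among genes of calcium handling and conduction, Cacnb2, a subunit of the L-type calcium channel, had a promoter signal value of 11.98, with 10.99 ± 4.17 (SD, n = 2) in the replicates. Kcnq1, the channel of the slow delayed rectifier current, had no promoter peak and 7 distal peaks. Kcnj3, Corin, Kcnj5 and Kcne1 also had no promoter peak in the joint list, the last 3 named after their values were seen. Among energy genes, the nuclear receptors Esrrg and Ppara had the highest signal values summed over promoter and distal peaks in the joint list, 48.5 and 40.1. In the replicates the sums were 25.4 ± 3.68 and 34.2 ± 7.60 (SD, n = 2), and that of Esrrg lay below Pdk4 at 33.2 ± 0.534, named after its value was seen. Their promoter signal values were 14.3, with 13.2 ± 0.281 (SD, n = 2) in the replicates, and 10.7, with 10.47 ± 0.5999 (SD, n = 2). Slc27a1, a fatty acid transporter with a promoter signal value of 5.93, was lowest by the sum. Among housekeeping genes the highest summed signal values were those of Ywhaz, a 14-3-3 protein with a promoter signal value of 8.76, and Eef1a1, a translation factor with 14.5. Chmp2a, with a promoter signal value of 5.25, was lowest by the sum.

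Ventricular and atrial genes differed in how many promoters had peaks, though the difference between these lists was not tested. Myl2, the ventricular myosin light chain gene, had a promoter signal value of 7.30, with 8.34 ± 0.147 (SD, n = 2) in the replicates. Gja1, which encodes connexin 43, had 6.94 in the joint list. Of the replicates' own lists, only that of replicate 2 held its promoter peak, at 8.71. Of 15 atrial genes, 5 (33.3%) had a promoter peak, within random lists (mean 47.9%). These were Nppb, Tbx5, Myl4, Pitx2 and Myl7, of which Myl4 and Pitx2 were named after their values were seen. Nppb, the gene of the B-type natriuretic peptide, had 11.2, with 10.6 ± 0.145 (SD, n = 2) in the replicates. Myl7, the atrial light chain gene, had 4.46 and no promoter peak in either replicate's own list. Nppa, the gene of the atrial natriuretic peptide, had no peak in the joint list. Its promoter had a peak of 5.87 in replicate 2's own list, none in replicate 1's, and one of 5.77 in the relaxed list. Kcna5 and Kcnj3, potassium channel genes, had no peak in the joint list. The atrial list stood below random in replicate 1, and in the joint list with the 5'-most start site alone (20%).

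Distal open chromatin gathered around genes of heart muscle and vessels. The 25 sarcomere genes had 46 distal peaks, 4.07-fold the mean of random lists matched on the length of genome nearest to each gene. The 24 cardiac transcription factors had 84 (3.73-fold), the 26 energy genes 36 (3.06-fold), and the 25 calcium and conduction genes 59 (2.61-fold). The 23 endothelial and endocardial genes had 42 (2.71-fold), and the 15 smooth muscle and pericyte genes had 19 (2.70-fold). The 25 housekeeping genes had 16 (2.22-fold). These 7 lists stood above the upper limit of random lists. The replicates' own lists had fewer distal peaks per gene: 1.28 ± 0.283 (SD, n = 2) against 1.84 for sarcomere genes, 2.21 ± 0.0589 against 3.50 for cardiac transcription factors, 0.904 ± 0.0272 against 1.38 for energy genes, 1.54 ± 0.141 against 2.36 for calcium and conduction, 1.15 ± 0.0922 against 1.83 for endothelial and 0.70 ± 0.0471 against 1.27 for smooth muscle genes. The first 4 and the endothelial list did so in both replicates' own lists too, whereas the smooth muscle and housekeeping lists were within random in replicate 1. The endothelial and smooth muscle calls ended among the upper 50% of peaks by signal value, and the housekeeping call ended in the relaxed list and with other gene assignments.

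In the joint list Mef2a had 10 distal peaks, Tead1 had 9, Kcnq1 had 7, and Nfatc1, a factor of endocardium and heart valves, had 6. Actn2, Esrrg, Hand2, Ywhaz and the type I collagen gene Col1a1 had 5 each. Myl2, Ppara, Cacnb2, Nkx2-5, Nppb, Xirp1 and Mylk, the gene of smooth muscle myosin light chain kinase, had 4 each. Myh7, Tbx5 and Eef1a1 had 3, Irx4 and Smtn had 2, and Tnnt2, Myh6, Myl7, Hand1 and Myom2 had 1. Kcnj3, Gja1, Nppa, Slc27a1 and Chmp2a had none. In the own lists of replicates 1 and 2, Mef2a had 4 and 6, Tead1 3 and 7, Kcnq1 7 and 5, Nfatc1 3 and 4, Actn2 4 and 3, Esrrg 1 and 2, Ppara 2 and 4, Cacnb2 2 and 3, Nkx2-5 3 and 2, Tbx5 1 and 2, Eef1a1 1 and 3, Hand1 1 and 0, and Myom2 2 and 0. Ywhaz had 3 in each, Hand2, Col1a1 and Nppb 2 in each, and Myl7 none. The ventricular list had 21 distal peaks (1.92-fold), within random lists for the joint list and above them in each replicate's own list. The atrial list had 19 (1.73-fold) and the fibroblast, epicardial and valve list 25 (1.39-fold), both within random.

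At the Gata4 gene (ENSMUSG00000021944.15, chromosome 14, 63198922 to 63271692), which encodes a zinc finger factor of heart development, the joint list had 2 promoter peaks, and 6 distal peaks were assigned to the gene. Its higher promoter peak spanned 63245168 to 63245750 with a signal value of 7.74, and 7.53 ± 0.171 (SD, n = 2) in the replicates. The peak at the upstream start site, 63271422 to 63272199, had 4.27 and was in neither replicate's own list. Intron peaks stood at 63247523 to 63248111 (6.61) and 63255544 to 63256438 (7.36), both found in each replicate. In the plotted region 3 intergenic peaks lay upstream of the gene, and the farthest of them, 63317452 to 63317823 (6.46), was in both replicates' lists.

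**Figure D2:**
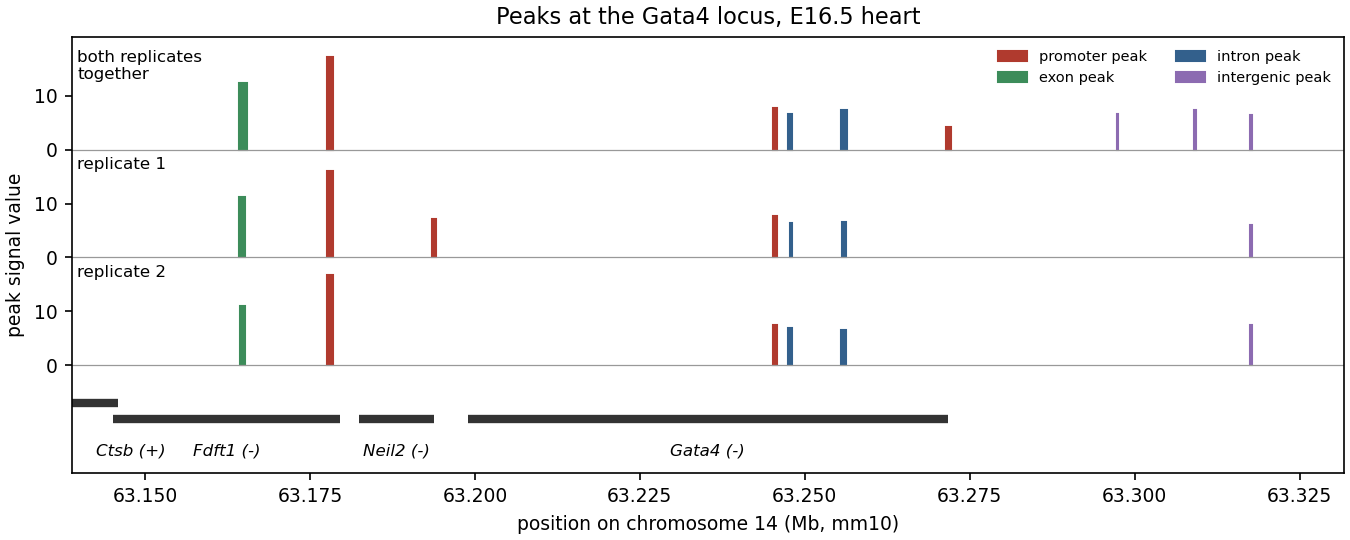
Peaks around Gata4 on chromosome 14 in the joint list and in each replicate, drawn at their position in Mb with the deposited signal value as height and the class as colour, above the protein-coding genes. The promoter peak of 7.74 and both intron peaks recur in each replicate's own list. The upstream promoter peak of 4.27 appears in the joint list and in neither replicate's own list.

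Promoters of the other cell types of the heart were open at shares inside those of random lists. The endothelial and endocardial list had 12 of 23 (52.2%, random mean 54.9%), the fibroblast, epicardial and valve list 9 of 22 (40.9%, 50.5%), and the smooth muscle and pericyte list 8 of 15 (53.3%, 36.2%). In the replicates' own lists the shares were 34.8% ± 0, 40.9% ± 12.9 and 33.3% ± 9.43 (SD, n = 2), within random in each replicate. Ets1, an endothelial transcription factor, had a promoter signal value of 13.4, with 13.2 ± 0.122 (SD, n = 2) in the replicates. Nfatc1 had 7.16, with 6.89 ± 0.672 (SD, n = 2). Cdh5, the gene of VE-cadherin, had 6.19 and Wt1, an epicardial factor, had 6.18. Of the replicates' own lists, only that of replicate 1 held a promoter peak for each. Col1a1 had 5.33 and Smtn, the gene of smoothelin, 7.98. Flt4, Col3a1, Meox1, Mylk and Lmod1 had no promoter peak in the joint list, and Flt4 had one of 9.14 in the own list of replicate 2. In the relaxed list these 3 lists stood above random, at 100%, 86.4% and 86.7%, and among the upper 50% of peaks the endothelial (13.04%) and fibroblast (18.2%) lists stood below.

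Genes of blood and of immune cells had few promoter peaks. The erythroid list had 3 of 20 (15%, random mean 21.8%), at Tspan33 (14.7), Nfe2 (7.83) and Epor (6.08), the latter pair named after their values were seen. The erythroid factors Gata1 and Klf1 and the heme synthesis gene Alas2 had none. The immune list had 1 of 21 (4.76%, random mean 18.6%), at Ikzf1, a lymphoid factor named after its value was seen. In the replicates' own lists the immune share was 0% ± 0 (SD, n = 2). Laptm5, Tyrobp and the complement gene C1qa had none. The erythroid share lay within random in the joint list (percentile 18.7) and in each replicate's own list (percentiles 10.1 and 30.7). The immune list lay within random for the joint list, at percentile 3.81, and below random in each replicate's own list (percentiles 1.08 and 1.19). Distal peaks numbered 2 at erythroid and 7 at immune genes, both within random.

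Promoters of other tissues were open less often than those of matched genes. The brain list had 3 of 22 (13.6%, random mean 70.9%), at Snap25 (11.2; 9.29 ± 2.04, SD, n = 2), Dlx1 and Syn1. The neural crest, glia and neuron list had 5 of 18 (27.8%, 60.5%), at Hand2, Mpz, Isl1, Elavl4 and Ngfr, and Hand2 and Isl1 are also in the list of cardiac factors. The lung and gut epithelium list had 1 of 21 (4.76%, 50.4%), at Krt19, and 0% ± 0 (SD, n = 2) in the replicates' own lists. Olfactory receptors had 1 of 1091 (0.0917%, 8.90%), at Olfr607. These 4 lists stood below the lower limit of random lists in the joint list and in both replicates' own lists. The liver list had 2 of 22 (9.09%, 22.6%), at Foxa3 and Apoh, and the skeletal muscle list 4 of 20 (20%, 35.1%), at Actn3 (17.9), Mylpf (10.4), Mymk and Myh8. Both lay within random, both fell below it with a promoter window of 500 bp (0% and 10%), and the skeletal list was below it in replicate 2. Genes in these counts other than Snap25, Hand2, Actn3 and Mylpf were named after their values were seen. Whether their promoter peaks also lay at the start site of a neighbouring gene was not examined.

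The forebrain factors Foxg1 and Emx2, the liver genes Alb and Afp, the epithelial cadherin gene Cdh1, the neuronal factor Ascl1, the myogenic factor Myod1 and the skeletal actin gene Acta1 had no peak in the joint list. Nes, the gene of nestin, had 2 distal peaks, Dbh 5, Ambp 3, Ttr 2, Scgb1a1 3 and Grhl2 2, all without a promoter peak there. In the own lists of replicates 1 and 2 these numbered 2 and 1, 3 and 3, 1 and 0, 0 and 1, 2 and 4, and 1 and 0. Among distal peaks, olfactory receptors had 20 over 1091 genes, 0.0923-fold the random mean and below it. Of those, Olfr1423 had 5, Olfr1402 had 2, against 0 and 2 in the replicates' own lists, and Olfr1 had none. The neural crest list had 18 distal peaks, brain 11, lung and gut epithelium 8, liver 6 and skeletal muscle 5, all within random lists.

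**Figure D3:**
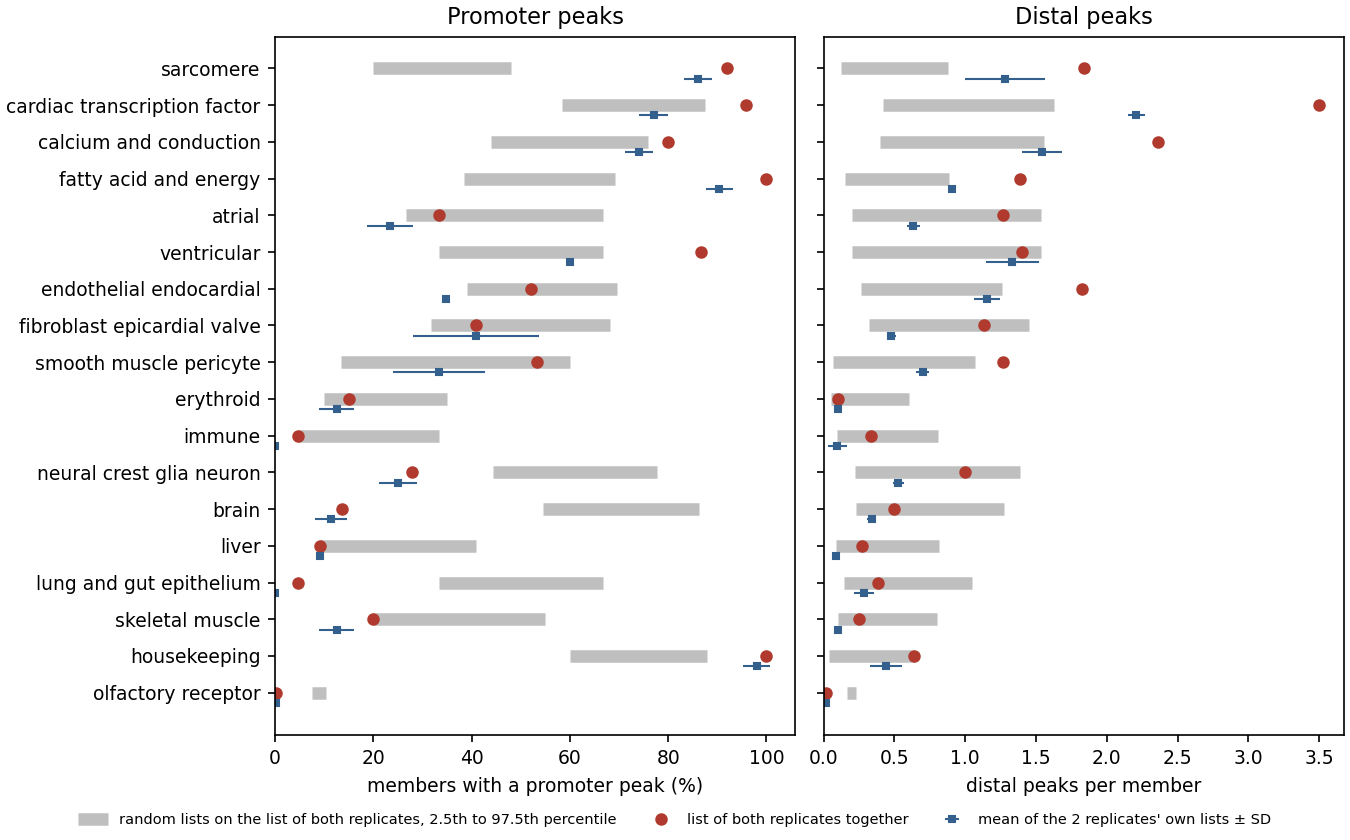
Share of each list's members with a promoter peak in percent (left) and distal peaks per member (right), with the joint list as circles, the mean ± SD of both replicates' own lists as squares, and the interval of random lists between its lower and upper limit in grey. Sarcomere genes stand above random in both panels (92% of members, 46 distal peaks), and brain and epithelial promoters stand below.

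Distal peaks held binding sequences of several cardiac and general factors more often than their flanks, though not those of TBX5 and of HAND or TAL factors. MEF2 sites, bound by factors that activate muscle genes, were in 7.96% of 12204 distal windows and 3.10% of flanks, a log2 ratio of 1.36 and 1.34 ± 0.03 (SD, n = 2) in the replicates. TEAD sites had a log2 ratio of 1.42, with 1.39 ± 0.07 (SD, n = 2). GATA sites were in 15.3% and 10.9%, a log2 ratio of 0.49, with 0.50 ± 0.03 (SD, n = 2). The serum response factor site had 0.77, MEIS 1.07 and NKX2-5 0.22. The sites with the highest ratios in the joint list were CTCF, an insulator protein, at 4.88, with 4.39 ± 0.22 (SD, n = 2) in the replicates, NFI at 3.79, with 3.97 ± 0.36 (SD, n = 2), and NRF1 at 3.42, with 4.43 ± 0.34 (SD, n = 2). ETS had 1.49, PU.1 1.31, with 0.87 ± 0.28 (SD, n = 2), the E-box CAGCTG 1.26, AP-1 1.05 and KLF or SP 1.01. NRF1 sites were rare, in 0.565% of distal windows and 0.0530% of flanks. Distal windows and their flanks were not matched on GC content, so an effect of base composition on the order of these ratios was not excluded. Distal peaks also include those at start sites of noncoding genes.

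The other 8 sites with a ratio were no more frequent than in flanks. Log2 ratios were -0.01 for the E-box CAGATG of HAND or TAL factors, -0.07 for SOX, -0.17 for ESRR, -0.18 for RUNX, -0.29 for TBX5, -0.32 for FOX, -0.65 for HNF4 and -1.55 for PITX. HNF1 and REST had no match in 1 of the compared sets, so no ratio was formed. In 11749 promoter windows the order differed, with NRF1 at 8.30, CTCF at 2.91, ETS at 2.69 and KLF or SP at 2.00, while MEF2 had -1.75 and GATA -2.16. Promoter windows and their flanks were not matched on GC content, so an effect of base composition on this order was not tested. Against genomic windows matched on GC content, the distal ratios were 3.66 for MEF2 and 1.495 for GATA, and with every summit as a peak they were 0.90 and 0.29. In the relaxed list MEF2 had 0.76, and the signs for SOX, ESRR, RUNX, FOX, HNF4 and CAGATG turned under at least 1 alternative.

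**Figure D4:**
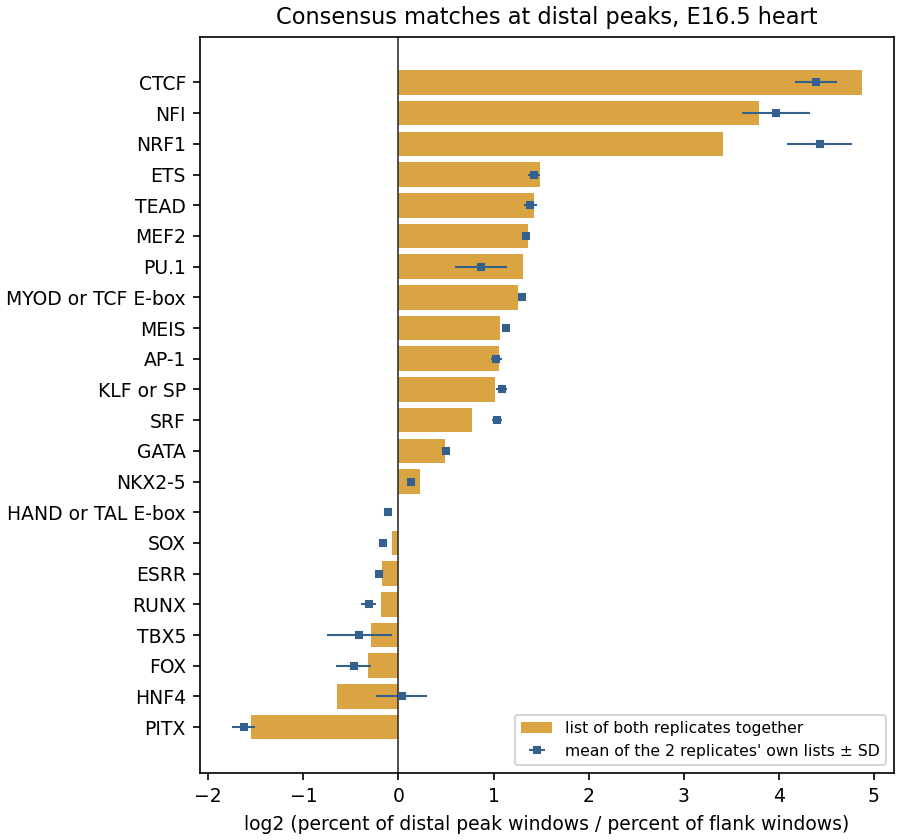
Log2 ratio of the share of distal peaks with a consensus match to that of flanking windows for each motif, with the joint list as bars and the mean ± SD of both replicates' own lists as squares. CTCF stands highest among bars at 4.88, MEF2 and GATA stand at 1.36 and 0.49, and PITX lies lowest at -1.55.

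Stitching of distal peaks gave 9803 clusters, 1732 of them with 2 or more peaks. Of the 20 with the highest summed signal value, 0 were nearest to a sarcomere, cardiac transcription factor or calcium and conduction gene, and random draws of 20 clusters gave a mean of 0.325 and at most 4, so a count of 0 did not differ from chance (percentile 36.1) and could not have stood below it. The 10 highest were nearest to Abcb11 (59.4), Scyl1 (56.3), Pak3 (55.7), Chd2 (55.3), Gm10181 (53.2), Tyrp1 (51.0), Lrrc74a (50.8), Gm5426 (49.6), G6pd2 (48.0) and Abt1 (46.6). Those of Abcb11, Pak3, Gm5426 and G6pd2 were single peaks, and all 3 peaks of the Tyrp1 cluster aligned to the mitochondrial genome. The cluster near Scyl1 (chromosome 19, 5786445 to 5827880) had 8 peaks and spanned the long noncoding RNA genes Malat1 and Neat1, both named after the values were seen. In the replicates its sum was 35.6 ± 6.30 (SD, n = 2), at ranks 188 and 44, that near Gm10181 was 33.3 ± 8.99, at ranks 96 and 727, that near Lrrc74a was 39.9 ± 8.25, at ranks 20 and 13, and that near Abt1 was 36.8 ± 19.96, at ranks 3 and 127. The other 6 of these 10 had ranks of 1 to 7 in both.

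The highest cluster nearest to a cardiac list gene was that of Xirp1 (chromosome 9, 120001770 to 120028140), at rank 33, with 4 peaks, a sum of 37.7 and 35.9 ± 2.27 (SD, n = 2) in the replicates. Clusters near Mef2d, Mef2a, Kcnq1 and Irx4 followed at ranks 46, 63, 81 and 104 in the joint list. The sum near Mef2d was 35.7 there and 23.6 ± 0.257 (SD, n = 2) in the replicates, and that near Mef2a was 33.5 and 13.2 ± 0.405. Mef2d was named after its value was seen. Of the 20 highest joint clusters, 11 were among the 20 highest of replicate 1 and 11 among those of replicate 2. The cardiac count was 1 in replicate 1 and 0 in replicate 2.

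Peaks were sparse on the sex chromosomes in these pools of both sexes. The X chromosome had 3.08 joint peaks per Mb against 9.51 on the autosomes, a ratio of 0.323, and 0.344 ± 0.00721 (SD, n = 2) in the replicates. The Y chromosome had 3 peaks in the joint list. Among autosomes, chromosome 11 was densest, at 14.8 per Mb, and chromosome 14 sparsest, at 7.23. Promoter peaks were listed for 365 of 948 X genes (38.5%) and for 55.2% of autosomal genes. No list held a peak on the mitochondrial chromosome.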

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

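The test of peaks with no stretch aligned to the mitochondrial genome was chosen only after the other alignments were seen. The other tests in this part were fixed after the pattern was seen and before their values were computed.

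Some peaks stand in data that the comparisons did not use. The deposited ranked list of both replicates held 184 summits with an IDR of 0.05 or less that the thresholded joint list leaves out. Of these, 49 lay on scaffolds outside the assembled chromosomes, in 23 intervals. The rest lay in 59 intervals on chromosomes, and 1 of them, at 24611586 to 24616163 on chromosome 1, aligned over 100% of its length to the mitochondrial genome at 99.96% identity. There were no control samples to set these against.

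Among distal peaks, 12 had a higher signal value than the highest promoter peak (27.97), all 12 were found in both replicates, and their median width was 354 bp against 556 bp for all distal peaks. Many further copies in the assembled sequence are argued against, since 0% of the 12 had 10 or more copies elsewhere. The share was also 0% in 200 other distal peaks, so the comparison does not set the 12 apart. Copies missing from the assembled sequence could not be counted, so reads from such copies stay open. Mitochondrial reads placed on nuclear copies stay open as the cause for the 12 as a set. Of these, 41.7% aligned over at least 50% of their length, between both bounds set in advance, against 0 of 200 other distal peaks. The nearest genes of the aligned peaks were Gm5426 (58941 bp away), Tyrp1 (831185), Nxph1 (940310), Galc (1181916) and G6pd2 (1765839). Nxph1 and Galc were named after their values were seen. The peak nearest to Abcb11 fell short, at 48.3% of its length with 100% identity. Ranked by -log10 p, the first 3 joint peaks aligned over 74.6%, 100% and 99.0%, and those at ranks 9 and 10 over 0%. Of the 7 nuclear copies of at least 200 bp with 95% identity or more, 85.7% overlapped a distal peak, against 1.39% of the 72 copies below 85% identity, so misplaced mitochondrial reads may account for peaks on close copies. For the 6 peaks with no aligned stretch, Pak3 and Frmd4a among them, mitochondrial reads are argued against, since 0 aligned even at 75% identity, their cause stays open, and no biological explanation was tested.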

How the results depend on the processing

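The tests chosen after seeing the data were those with every summit as a peak, with the 5'-most start site, with clusters lacking mitochondria-like peaks or of at least 2 peaks, and the X ratio without each replicate. Where a value moved, the cause was not tested unless stated. No paired analysis was possible, because there was 1 group.

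The mean replicate overlap of 81.1% was 78.4% with reciprocal overlap, 83.7% in the upper 50% of peaks by signal value and 69.1% in the relaxed lists. It moved by less than 2.27 percentage points with 1 shared base or with the summit inside the other peak. This yardstick is the SD between the 2 directions of the same comparison and not a spread between replicates. Spearman's correlation of signal values was 0.753 in the upper 50%, where the range of values is narrower by construction, and changed by under 0.05 in the relaxed lists and with -log10 p in place of signal. Division by each list's median cannot change a rank correlation. Restricted peaks numbered 6194 when searched in the thresholded list and 17 in the upper 50%. The promoter share of 49.1% was 68.4% in the upper 50%, 25.4% in the relaxed list, 50.1% in the pooled pseudoreplicate list, and 58.9% to 60.3% without each replicate. It was 46.3% with a window of 500 bp, 51.5% with 2000 bp, 55.2% with start sites of all genes, 50.1% with any base of the peak and 60.9% with every summit. The X ratio of 0.323 was 0.275 in the relaxed list, 0.439 in the upper 50%, and 0.339 to 0.349 without each replicate.

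For promoter peaks, 6 lists stood above and 4 below random, and these counts became 1 and 7 in the upper 50%, where cardiac transcription factors turned from above to below at 37.5%. With unmatched random lists 8 stood below, the erythroid, immune, liver and skeletal muscle lists added. For distal peaks, 7 stood above and 1 below, and 2 stood below in the relaxed list and 2 with unmatched lists. In the other alternatives both counts stayed within 1.5 times their main values, and lists crossed a limit in single cases: leaving out either replicate moved 4 of 18 promoter lists. The number of cardiac clusters among the 20 highest was 0 to 1 without each replicate and 1 when ranked by number of peaks, and it was 0 in the 7 other alternatives.

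The log2 ratio of GATA, 0.49, was 0.44 in the relaxed list, 0.62 in a window of 50 bp, 1.495 against GC-matched windows, 0.29 with every summit, and 0.48 to 0.52 without each replicate. That of MEF2, 1.36, was 0.76, 1.68, 3.66 and 0.90 in the same order, 1.27 in the pooled pseudoreplicate list and 1.31 to 1.36 without each replicate. Signs turned in the relaxed list for the E-box CAGATG (0.17), SOX (0.082), RUNX (0.32) and ESRR (0.12). They turned against GC-matched windows for SOX (0.14), FOX (0.50), RUNX (0.52) and ESRR (0.57), for HNF4 among the values without each replicate (-0.16 to 0.22), and for CAGATG with every summit (0.018). Of the 22 motifs with a ratio, 15 moved by over 1 SD without a change of sign against GC-matched windows, and 13 in the upper 50%. HNF1 and REST gave no main ratio and were not compared. The unknown depth limits every statement on genes without a peak.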

Other observations

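The gene groups in this part, and their comparison with random lists, were chosen only after the results for the fixed lists were seen. The comparison of GC content between the peak sets was added after the MEF2 percentiles were seen, and the bound set before them was kept. The other tests on the X chromosome and on MEF2 sites were fixed after those patterns were seen and before their values were computed.

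Promoters of the HOX genes, which pattern the body axis, had almost no peaks. Of 39 HOX genes 1 had a promoter peak (2.56%), Hoxa1 at 7.74, against 70.9% in lists matched on CpG content. The B, C and D clusters had 0. Other families below matched lists were the clustered protocadherins (1 of 55, Pcdhgc3, against 59.2%), vomeronasal receptors (1 of 327, Vmn1r4, 8.16%), keratins (3 of 49, Krt10, Krt19 and Krt80, 30.7%), claudins (4 of 23, Cldn5, Cldn10, Cldn11 and Cldn12, 38.6%) and collagens (12 of 44, 50.4%). Fox factors (21 of 44, 74.6%), Sox factors (9 of 19, 77.0%), potassium channels named Kcn (25 of 92, 56.1%) and interleukins with their receptors (13 of 68, 30.5%) also lay below. Ribosomal proteins (77 of 80, 82.5%), subunits of NADH dehydrogenase (35 of 36, 79.4%) and zinc finger genes named Zfp (294 of 365, 62.4%) lay above. Histones (58 of 67, 88.2%), laminins (8 of 11, 48.7%) and Tbx factors (6 of 13, 52.6%) lay within. These shares are of the joint list. In the replicates' own lists they were 1.28% ± 1.81 for HOX genes, 4.55% ± 1.29 for protocadherins and 3.06% ± 1.44 for keratins (SD, n = 2). Claudins had 8.70% ± 0 and Tbx factors 30.8% ± 0 there (SD, n = 2). The members named here were chosen after their values were seen.

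The genes with the most distal peaks in the joint list were Sorbs1, an adaptor of the actin cytoskeleton and insulin signalling, with 14, and Sh3pxd2a, a podosome scaffold, with 13. Kalrn, Tns1, Irf2bpl and Zmiz1 had 12 each, and Tgfbr3, a coreceptor for TGF-beta, Nav2 and Casz1, a zinc finger factor, had 11 each. The own lists of replicates 1 and 2 had 10 and 7 for Sorbs1, 3 and 4 for Sh3pxd2a, 9 and 9 for Kalrn, 9 and 11 for Tns1, 5 and 10 for Irf2bpl, 6 and 6 for Zmiz1, 3 and 5 for Tgfbr3, 6 and 4 for Nav2, and 4 and 5 for Casz1, so the order did not hold there. These genes were named after their values were seen.

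The X chromosome had a peak density 0.323 of that of autosomes. Fewer genes (0.659 of the autosomal number per Mb) and CpG-poorer promoters are argued against as the whole cause, since X genes with a promoter peak (38.5%) lay at percentile 0 of matched autosomal lists (41.8% to 46.6%), although the ratio to matched lists, 0.873 in the joint list, was 0.990 (0.922 to 1.07) in the upper 50% of peaks. Fewer X copies, and so fewer reads, were to bring this ratio nearer 1 in the relaxed list, but it fell by 0.0279 (interval from -0.0702 to 0.0145), beyond the bound set against that explanation. After this value was seen the bound was judged wrong, because the relaxed list has a threshold of its own that depends on reads, but the tables do not decide: the ratio near 1 in the upper 50% holds for promoters alone, and the distal density ratio, 0.191 in the joint list, was still 0.311 there. Fewer X copies may therefore contribute and cannot be told apart from other causes without read counts, and no biological explanation was tested.

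A hypothesis was that distal peaks nearest to sarcomere, cardiac transcription factor and calcium genes hold MEF2 sites more often than other distal peaks. Of 189 such peaks 23 (12.2%) had a site, against 7.90% of the others, at percentile 98.6 of sets matched on signal value, in line with the hypothesis. Lower GC content is argued against as the cause, since the median was 54.2% in both sets, matching on GC content as well raised the mean of random sets only from 7.72% to 7.86%, and the percentile was then 98.5. Replicate 1 alone gave 15.4% (percentile 99.9) and replicate 2 alone 11.1% (percentile 91.7), which is within random sets, so the call was not met in replicate 2. Of 8 motifs examined, GATA (24.9% against 15.1%) and SRF (4.76% against 1.49%) also lay above the upper limit of such sets in the joint list and in both replicates. The 189 peaks belong to at most 74 genes, with 10 at Mef2a alone, whereas random sets were drawn peak by peak. Peaks of the same gene are not independent, so the percentiles for all these motifs may be too extreme.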
